A study of Homo sapiens with 8 samples.

How the data were processed

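The series compared a miR-517a-3p mimic with a negative-control mimic in the choriocarcinoma lines BeWo and JEG3 after 24 h of transfection, with 2 libraries per group and 8 in all. Per the labels' protocols, total RNA was extracted with the miRNeasy mini kit and paired-end sequencing was done by a service provider. Each library was assigned to its group by its title. In the deposited table the control columns carry the abbreviation NC, which was read as the negative-control mimic that the labels' treatment protocol names.

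The deposited table holds TPM, an abundance normalized for transcript length and library total, per Ensembl transcript for the 8 libraries. Its name speaks of counts, but its values are not whole, and the sum over unique transcripts is the TPM total in each library. Per the submitters' processing notes the quantification tool was kallisto, with no version given, and the build was GRCh38. The release of the transcript annotation is not given in the sources used here. The table had 193845 rows, of which 1958 repeated a transcript and were dropped, which left 191887 transcripts. TPM was summed over the transcripts of each gene symbol the table gives, 28909 in all, with no further normalization. Another 9542 transcripts without a symbol held between 1.03% and 1.31% of the TPM of a library and were tested apart. TPM keeps no record of sequencing depth, so no counting interval can be given, and the precision of each value rests on the spread between libraries. Since the total is fixed, a rise of abundant RNAs lowers all other values.

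A count test, the rule for named genes, the gene lists and most alternatives were fixed before the data were examined. Because the values are TPM, the main test was instead limma-trend (limma 3.58.1 in R 4.3.3, with trend and robust moderation) on log2(TPM + 1). These settings were chosen once the unit was known, and a first look at the fit used the same ones. One model with a mean for each of the 4 groups was fitted to the 8 libraries, with 4 residual degrees of freedom and a median of 4.58 prior ones. Genes at 1 TPM or more in every library of at least 1 group were kept, 13553 in all, of which 12644 are protein-coding. Comparisons were mimic minus control in each line, their average and their difference, and control JEG3 minus control BeWo. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Under the rule for named genes, for each within-line comparison, the difference and the control comparison, the text took the 10 largest rises and falls among called genes with an average log2(TPM + 1) of at least 2. Within lines, both mimic libraries also had to lie on the same side of both control libraries. The rule further took the 10 largest shared rises and falls, the 10 8mer genes with the largest mean fall, and from each list up to 4 called members by smallest adjusted p, or the 2 most abundant members where none was called. It always took the 3 reported targets. The average threshold had been planned on another scale and was kept at the same number. Y-linked genes and XIST were left out of the named genes as an exception.

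Seed sites were searched in 3' UTRs of GENCODE v29 transcripts on GRCh38, taking the most abundant coding transcript of each gene. Of the 191887 transcripts 168749 are in that release, and 12569 tested genes had a 3' UTR. The mature sequence AUCGUGCAUCCCUUUAGAGUGU gave the sites. The shift is the median log2 fold change of genes with a 7mer or 8mer minus that of genes without a 6mer, with an SE from 500 bootstrap resamples. It was compared with 299 control 7-mers of the same base composition and CpG number. There were 28 gene lists with 761 symbols, and 756 symbols were found in the table. The 25 lists with at least 5 tested members were tested by camera with a preset inter-gene correlation of 0.01 and again with an estimated one, and by fry, on log2(TPM + 1) in place of the planned voom values. No list call held with the estimated correlation. Benjamini-Hochberg adjustment ran over the 25 lists of each comparison.

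The lists were the reported targets; syncytiotrophoblast, cytotrophoblast and extravillous trophoblast genes; NF-kappaB and interferon responses; S-phase and G2/M genes; p53 targets and apoptosis regulators. Further lists were hypoxia and glycolysis, sterol synthesis, unfolded protein and integrated stress responses, adhesion and epithelial-mesenchymal transition, TGF-beta, MAPK feedback and YAP targets, and angiogenic factors. The others were the microRNA machinery, imprinted genes, steroidogenesis, ribosomal proteins, mitochondrially encoded RNAs, histones, and markers of fibroblasts, endothelium, leukocytes and carcinoma epithelia.

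Within groups, libraries correlated at 0.989 to 0.990 on the log2 scale, and exactly equal values above 0 were found for at most 1 gene in any pair of libraries. Alternatives were median-ratio size factors on TPM, no filter, a filter of 10 TPM, protein-coding genes, the libraries of 1 line, an additive model, a block for the replicate number, and leaving out each library in turn. Pseudocounts of 0.1 and 5 and the removal of mitochondrial genes were added after seeing the data. With 1 library left out, the lone sample of its group is assumed to vary like the other groups. The procedures were also tested on simulated data after the real fit. Of 100 genes changed by 0.5 on the log2 scale among 13553, 55% were recovered in the BeWo and 46% in the JEG3 simulation. Of 100 changed by 1, 89% and 87% were recovered, with 10 false calls among all 154 calls in the BeWo and 8 among 141 in the JEG3 simulation. The real fits called 3884 genes in BeWo and 4760 in JEG3, far more than were changed in the simulations. The cut-off of an adjusted p depends on that number, so these shares do not carry over to the real fits. A seed shift of -0.3 was recovered as -0.306 and -0.31, and 0 of 25 lists were called where no effect had been set. The simulated noise was independent between genes, whereas the estimated correlation in the real data reached 0.471 for the mitochondrial list. These runs therefore could not show false list calls that arise when genes of a list vary together. Tables were handled in python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.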

Results

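RNA was measured by paired-end sequencing in BeWo and JEG3, 2 human choriocarcinoma lines that are widely used as models of placental trophoblast. The cells had been transfected for 24 h with a mimic of miR-517a-3p, a placental microRNA from a primate-specific cluster on chromosome 19, or with a negative-control mimic. The 4 groups of cell line and mimic held 2 libraries each, 8 in all. The deposited values were TPM (abundance per transcript, normalized for length and library total), summed here to genes. TPM has a fixed total, so the sequencing depth of the libraries is unknown. Between 12433 and 13077 genes reached 1 TPM in a library, and 13553 genes were tested. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are given as mean TPM ± SD (n = 2 libraries). Changes are log2 fold changes of TPM + 1 (mimic minus control unless stated) ± SE, with Benjamini-Hochberg adjusted p from limma. This scale understates the change of low genes.

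The first question was whether transcripts that can pair with the seed of the microRNA were lower in the mimic libraries. 3 genes had been listed beforehand as reported targets. TNIP1, an inhibitor of NF-kappaB signalling, went from 38.1 ± 1.57 to 19.9 ± 0.736 TPM in BeWo (-0.91 ± 0.075, adjusted p = 0.000114) and from 79.3 ± 2.52 to 50.6 ± 2.64 TPM in JEG3 (-0.64 ± 0.075, adjusted p = 0.000386). PTK2B, a focal adhesion tyrosine kinase, fell in BeWo (-0.71 ± 0.10, adjusted p = 0.00174) and in JEG3 (-1.01 ± 0.10, adjusted p = 0.000222). PRKG1, the cGMP-dependent protein kinase 1, was near the detection floor in BeWo, at 0.352 ± 0.0529 TPM in the control libraries, and did not pass there (-0.20 ± 0.18, adjusted p = 0.458). In JEG3 it fell from 3.65 ± 0.605 to 1.85 ± 0.497 TPM (-0.71 ± 0.18, adjusted p = 0.016). This call was lost without JEG3 control replicate 1 (change -0.58) or JEG3 mimic replicate 1 (-0.53), and with pseudocount 0.1 (adjusted p = 0.061). Adjusted over the list alone, 2 of the 3 genes passed in BeWo and 3 in JEG3. No row of the table named a MIR517 locus, so the level of the microRNA itself was not measured here.

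Among genes with an annotated 3' UTR, 249 held a 7mer or 8mer seed site of miR-517a-3p, and 11932 held not even a 6mer. The sites were the 8mer TGCACGAA, the 7mer-m8 TGCACGA, which pairs with positions 2 to 8, and the 7mer-A1 GCACGAA, which pairs with positions 2 to 7 and ends in an A. The median change of the genes with a site lay below that of the genes without by -0.35 (bootstrap SE 0.028) in BeWo and by -0.23 (SE 0.042) in JEG3. In BeWo 117 of the 249 genes fell and 3 rose, so 47.0% fell against 18.0% of the genes without a site. In JEG3 100 fell and 11 rose, so 40.2% fell against 21.3%. The gene set test camera gave p = 3.81e-12 in BeWo and p = 1.68e-06 in JEG3, and p = 0.0103 and p = 0.0346 with an estimated correlation. The median change by class in BeWo was -0.44 for 37 genes with an 8mer, -0.41 for 120 with a 7mer-m8, -0.40 for 92 with a 7mer-A1, -0.19 for 388 with a 6mer and -0.057 for those without. In JEG3 the same classes stood at -0.37, -0.28, -0.27, -0.097 and -0.060. The 8mer median had a bootstrap SE of 0.108 in BeWo and 0.145 in JEG3, more than its distance from either 7mer class. The order of the 8mer and 7mer classes was therefore not resolved. Of the 8mer, 7mer-m8 and 7mer-A1 genes 45.9%, 45.8% and 48.9% fell in BeWo, and 45.9%, 40.8% and 37.0% in JEG3. The 6mer median in JEG3 had an SE of 0.025. The shift was smaller without a filter on low values (-0.15 in BeWo and -0.097 in JEG3) and with a pseudocount of 5 (-0.23 and -0.15), and in JEG3 larger among genes at 10 TPM or more (-0.36).

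An 8mer site and a fall in both lines were found for 14 genes. ADAM9, a membrane metalloprotease, had the largest mean fall of these: from 134 ± 1.73 to 35.2 ± 1.36 TPM in BeWo (-1.89 ± 0.062, adjusted p = 3.8e-06) and from 164 ± 0.0378 to 54.95 ± 3.1 TPM in JEG3 (-1.56 ± 0.062, adjusted p = 8.24e-06). Its site lay in the 3' UTR at chromosome 8, 39104173 to 39104180, plus strand of GRCh38, within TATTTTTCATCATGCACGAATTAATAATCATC. PTGES, a prostaglandin E synthase, fell by 1.44 (0.067 SE) in BeWo and 1.16 (0.067 SE) in JEG3, with its 3' UTR site at chromosome 9, 129739390 to 129739397, minus strand, within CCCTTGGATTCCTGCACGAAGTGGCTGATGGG. The chloride channel protein CLIC4 fell by 1.14 and 0.94 in the same order, and its site was at chromosome 1, 24841032 to 24841039, plus strand. TMEM30A, a subunit of phospholipid flippases, fell by 1.08 in BeWo and 1.03 in JEG3 (site at chromosome 6, 75254468 to 75254475, minus strand). The splicing factor SMU1 fell by 1.22 and 1.05, and CDC42SE2 by 1.14 and 1.32. Changes of -0.89 and -0.82 were measured for STXBP1, -0.83 and -0.80 for UBR7, -0.73 and -1.13 for TARS3, and -0.63 and -0.94 for PRTG. The TARS3 call in BeWo was lost without BeWo control replicate 1 (adjusted p = 0.0940) or 2 (0.0639) and without BeWo mimic replicate 2 (0.111). The 8mer of TNIP1 lay in its 3' UTR at chromosome 5, 151029978 to 151029985, minus strand, within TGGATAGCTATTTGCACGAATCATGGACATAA. The PTK2B site, a 7mer-m8, was in the 3' UTR at chromosome 8, 27458635 to 27458641, plus strand. For PRKG1, the remaining reported target, this search found no 7mer or 8mer site, so its fall in JEG3 is not tied to a seed site here.

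**Figure D1:**
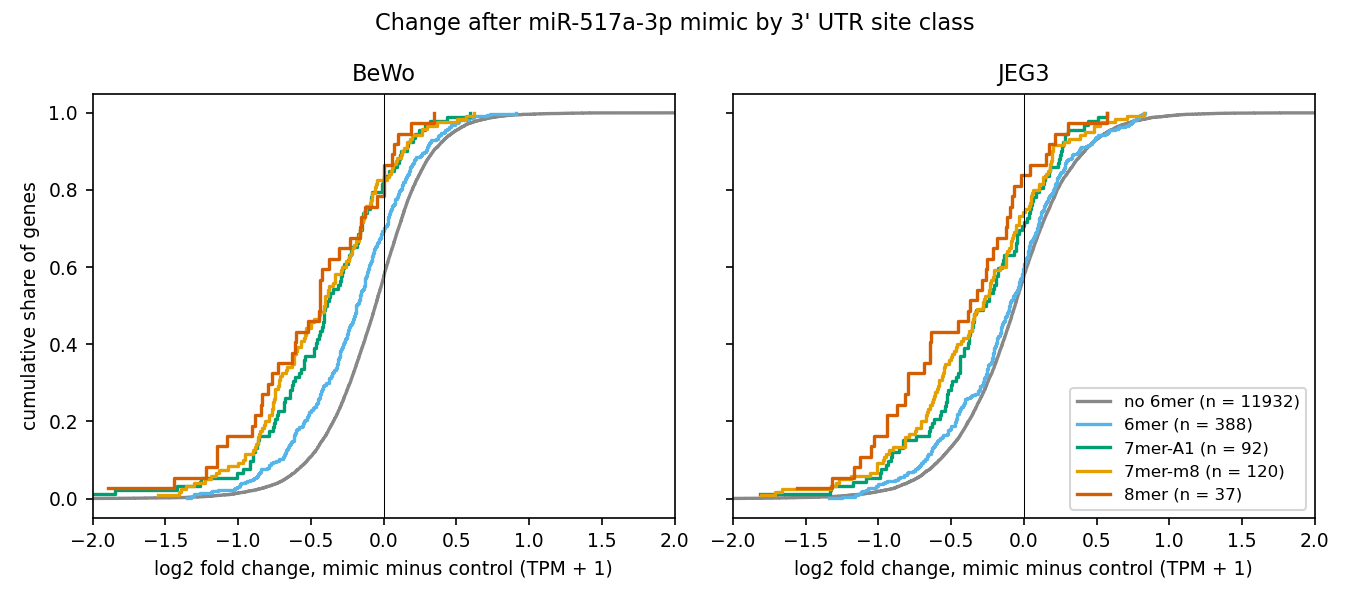
Cumulative share of genes (vertical axis) by log2 fold change of TPM + 1, mimic minus control (horizontal axis), in BeWo and JEG3, with 1 line per class of 3' UTR site. The lines of the 8mer and 7mer classes lie to the left of the line of the 11932 genes without a 6mer, and the 6mer line lies between them.

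In BeWo, the mimic libraries had lower levels of the growth factor IGF2, the collagen COL6A3 and the interferon-induced membrane protein IFITM1, and higher levels of the stress transcription factor DDIT3 and the endoplasmic reticulum protein CALU. IGF2 went from 32.9 ± 0.0605 to 5.16 ± 0.584 TPM (-2.46 ± 0.087, adjusted p = 3.8e-06), and it carries a 7mer-A1 site in its 3' UTR. COL6A3 went from 9.66 ± 0.393 to 1.58 ± 0.0523 TPM (-2.04 ± 0.14, adjusted p = 4.86e-05) and IFITM1 from 37.5 ± 3.07 to 9.93 ± 0.632 TPM (-1.82 ± 0.10, adjusted p = 1.57e-05). DDIT3 rose from 13.6 ± 1.15 to 37.99 ± 1.04 TPM (1.42 ± 0.084, adjusted p = 2.24e-05) and CALU from 99.2 ± 1.51 to 262 ± 20.6 TPM (1.39 ± 0.056, adjusted p = 5.08e-06). The other genes with the largest falls were RAB40B (-1.97), the actin-binding CNN2 (-1.93), the mitochondrial carrier SLC25A23 (-1.90), ADAM9, NTAN1 (-1.85, with a 7mer-A1 site) and the Rab GTPase-activating protein TBC1D1 (-1.75). Among the largest rises were the zinc finger gene ZNF439 (2.31), the homeobox gene DPRX (1.59), the histone H2AW (1.44), the gastrin gene GAST (1.38) and the mitochondrial phosphatase PTPMT1 (1.37). The pseudogenes RPL39P36 (1.65) and RPL32P29 (1.51) are uncertain, because reads can be split between near-identical copies. The same holds for TMEM183B, listed at 0 in both control libraries and at 2.66 TPM on average with the mimic, and for RNA5SP217, at 13.4 TPM in control and listed at 0 in both mimic libraries.

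Of 13553 genes, 1407 rose and 2477 fell in BeWo (28.7% of genes), 338 and 1046 of them by more than 1.5-fold and 61 and 220 by more than 2-fold. With median-ratio size factors in place of the fixed TPM total the split was 1857 up and 1996 down. The total of 3884 was 2395 without BeWo control replicate 1, 2242 without BeWo control replicate 2 and 2515 without BeWo mimic replicate 2.

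In JEG3, the mimic libraries had higher levels of the natriuretic peptide gene NPPB, the matrix metalloprotease MMP2, the collagen COL5A1 and the syndecan SDC1, and lower levels of the carnitine acetyltransferase CRAT and the ferrireductase STEAP3. NPPB went from 0.536 ± 0.255 to 10.9 ± 0.569 TPM (2.96 ± 0.19, adjusted p = 3.25e-05), MMP2 from 3.98 ± 0.393 to 14.7 ± 0.432 TPM (1.66 ± 0.084, adjusted p = 2.37e-05) and COL5A1 from 13.03 ± 1.28 to 40.2 ± 0.434 TPM (1.56 ± 0.14, adjusted p = 0.000105). SDC1 rose from 51.5 ± 4.89 to 149.7 ± 6.7 TPM (1.52 ± 0.15, adjusted p = 0.000154). CRAT fell from 38.3 ± 3.79 to 9.08 ± 0.677 TPM (-1.96 ± 0.094, adjusted p = 2.22e-05) and STEAP3 from 10.5 ± 0.149 to 2.04 ± 0.149 TPM (-1.92 ± 0.10, adjusted p = 2.37e-05). Other large rises were those of DPRX (2.22), CALU (1.54), the lysosomal glycoprotein CD68 (1.64) and ANKRD23 (1.76). Among the largest falls were C6orf141 (-2.11), the axonemal dynein gene DNAI1 (-1.97), SMIM1 (-1.91), the crystallin CRYBA2 (-1.91) and the corepressor RCOR2 (-1.84). The readthrough gene NME1-NME2 (2.02), the pseudogene RPL32P29 (1.82) and the antisense RNA RAB6C-AS1 (-2.71) are uncertain for shared reads. So are RDM1P4, at 7.55 TPM in control, and RNA5SP18, at 3.44 TPM, both listed at 0 in the mimic libraries. RDM1P4 in JEG3 lost its call without JEG3 control replicate 1 (adjusted p = 0.0638), JEG3 mimic replicate 1 (0.0797) or JEG3 mimic replicate 2 (0.0808), and with pseudocount 5 (0.0776).

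In this line 1883 genes rose and 2877 fell (35.1% of genes), 577 and 1300 by more than 1.5-fold and 107 and 285 by more than 2-fold. With size factors the split turned to 2577 up and 2262 down, and without mitochondrial genes it moved the other way, to 1616 up and 3289 down. Without JEG3 mimic replicate 1 the split was 1208 up and 2038 down, and without replicate 2 of that group 1331 and 2056.

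Whether the lines responded alike was asked next. DPRX, CALU, CD68, the zinc finger gene ZNF439, the TNF receptor TNFRSF1B, the epithelial transcription factor GRHL3, the Golgi protein GOPC and ERVFRD-1, the syncytin-2 gene, rose in both lines. CALU rose by 1.39 in BeWo and 1.54 in JEG3, TNFRSF1B by 1.25 and 1.03, GRHL3 by 1.36 and 1.05, GOPC by 1.11 and 1.06, and ERVFRD-1 by 1.01 and 1.11. The genes with the largest falls in both lines were NTAN1 (-1.85 and -1.81), the AP-1 repressor JDP2 (-1.71 and -1.71), CNN2 (-1.93 and -1.69), RAB40B (-1.97 and -1.67), the proton pump subunit ATP6V1B1 (-1.61 and -1.79), ADAM9, SMIM1 (-1.53 and -1.91), SPON2 (-1.68 and -1.44), C6orf141 (-1.37 and -2.11) and CITED4 (-1.35 and -1.77). Among these falling genes, a 7mer or 8mer site was found only for NTAN1 and ADAM9. In all, 751 genes rose in both lines against 195.5 expected of independent lists, and 1379 fell in both against 525.8. With size factors these counts were 1103 and 1021, and without BeWo control replicate 2 the sum of 2130 was 1359 under the main scaling. In opposite directions, 45 genes rose in BeWo and fell in JEG3 and 69 did the reverse, 114 against 642.8 expected. The calls of both lines rest on 1 shared variance estimate per gene, so they are not independent. A gene with a small variance is more easily called in both lines, whichever way it moves. The expected counts are therefore only a reference, and the size of the excess was not tested. Across the 13553 genes, which are not independent replicates, the log2 fold changes of the lines correlated at Pearson's r = 0.486 and Spearman's rho = 0.504, and the comparisons share no library. On average over both lines 2198 genes rose and 3731 fell (3032 and 2888 with size factors).

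**Figure D2:**
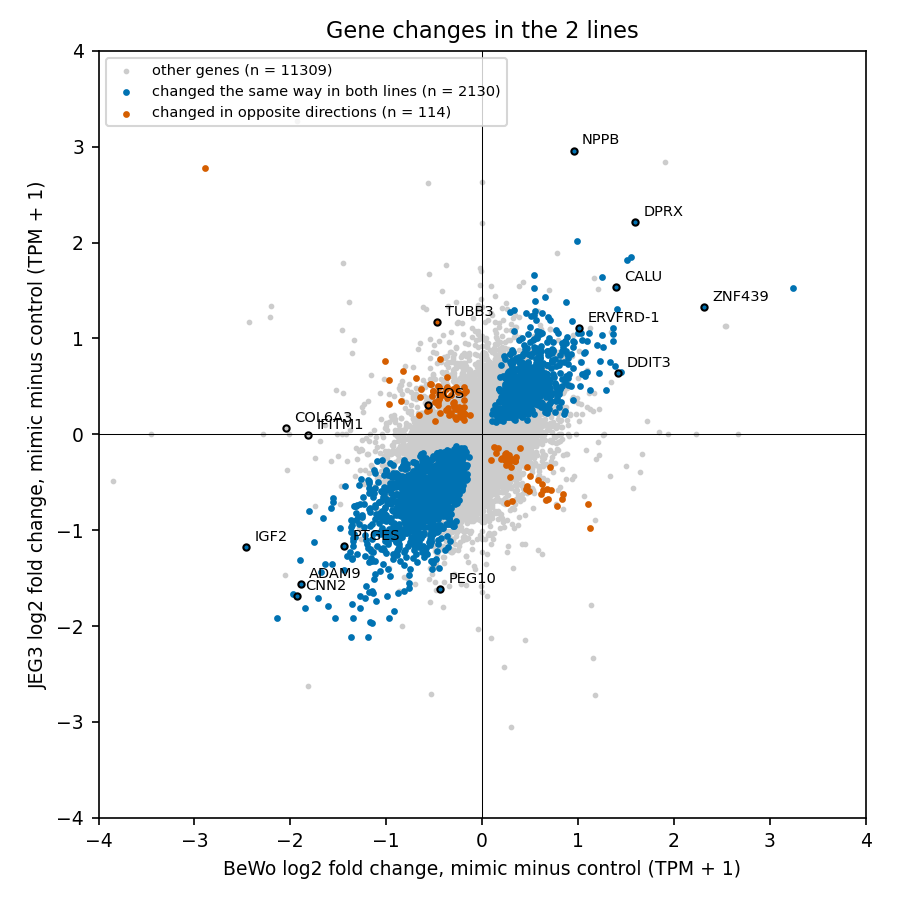
Each point is 1 of 13553 genes, with its log2 fold change of TPM + 1 in BeWo on the horizontal axis and in JEG3 on the vertical axis. Coloured points passed the test in both lines: 2130 moved the same way and 114 in opposite ways.

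Of the genes of the syncytiotrophoblast, the multinucleate outer layer of the placental villus that secretes its hormones, in BeWo 13 rose and 3 fell of 33 tested (13 and 4 adjusted over the list alone), and in JEG3 21 rose and 1 fell (21 and 1 adjusted over the list alone). Camera gave adjusted p = 0.000356 in BeWo and 8.75e-09 in JEG3, and adjusted p = 0.51 and 0.0976 with an estimated correlation. CGA, the alpha subunit of chorionic gonadotropin, rose from 165 ± 6.23 to 398 ± 22.4 TPM in BeWo and from 2307 ± 66.6 to 4348 ± 34 TPM in JEG3 (1.27 ± 0.048, adjusted p = 3.8e-06 in BeWo and 0.91 ± 0.048, adjusted p = 2.37e-05 in JEG3). The estrogenic dehydrogenase HSD17B1 rose by 1.23 and 0.76, the placental growth factor PGF by 0.56 and 0.90, and the cytokine GDF15 by 0.79 and 1.06. The list median was 0.15 in BeWo (0.096 without BeWo control replicate 1 and 0.554 for the 22 members kept at 10 TPM or more) and 0.56 in JEG3. The hCG beta, PSG, CSH, ERVV and galectin members share near-identical sequences, so their values are uncertain. Without these families the list median was 0.55 in BeWo and 0.75 in JEG3, over 20 members. Of these 20 members 11 rose in BeWo and 16 in JEG3. Most rises of the list therefore lay outside these families, and few of the family members were called as rising.

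Of the genes of the unfolded protein and integrated stress responses, more rose than fell in each line. In BeWo 19 rose and 4 fell of 36 tested (20 and 5 adjusted over the list alone), and in JEG3 21 rose and 3 fell (22 and 5 adjusted over the list alone). The endoplasmic reticulum chaperone HSP90B1 rose from 1846 ± 29.8 to 2960 ± 68.9 TPM in BeWo and from 957 ± 16.8 to 1385 ± 9.21 TPM in JEG3, and the disulfide isomerase PDIA4 by 1.09 and 0.98. The amino acid transporter SLC7A5, which has a 6mer site, fell in both lines (-1.32 and -0.74). The camera test gave adjusted p = 1.17e-07 and 3.51e-07, and adjusted p = 0.532 and 0.324 with an estimated correlation.

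Of the mitochondrially encoded RNAs, in BeWo 7 rose and 0 fell of 13 tested (9 and 0 adjusted over the list alone), and in JEG3 0 rose and 12 fell (0 and 12 adjusted over the list alone). MT-CO3, a cytochrome oxidase subunit, went from 6861 ± 215 to 8162 ± 151 TPM in BeWo and from 10950 ± 219 to 8768 ± 102 TPM in JEG3. MT-ND1 changed by 0.091 and -0.27, MT-ND3 by -0.011 and -0.36, and MT-ND6 by 0.12 and -0.41, of which MT-ND3 and MT-ND6 did not pass in BeWo and MT-ND1 passed there in 2 of the 8 fits without 1 library. These RNAs held 12.5% ± 0.716 of the TPM in BeWo control, 14.8% ± 0.940 in BeWo mimic, 12.9% ± 0.026 in JEG3 control and 10.3% ± 0.174 in JEG3 mimic libraries (SD, n = 2). With camera the list had adjusted p = 0.000343 in BeWo and 1.22e-05 in JEG3, and adjusted p = 0.57 and 0.324 with an estimated correlation. Among ribosomal protein genes, in BeWo 4 rose and 10 fell of 53 tested (4 and 10 adjusted over the list alone) (adjusted p = 0.878), and in JEG3 18 rose and 2 fell (18 and 2 adjusted over the list alone) (adjusted p = 1.22e-05, and adjusted p = 0.501 with an estimated correlation). RPLP1 changed by -1.08 and -0.70, RPL7A by -0.84 and -0.52, RPL3 by -0.03 and 0.24, and RPL11 by 0.068 and 0.24, neither RPL3 nor RPL11 passing in BeWo. By fry the mitochondrial call in BeWo (adjusted p = 0.0515) and the ribosomal call in JEG3 (adjusted p = 0.0778) did not pass.

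Of the G2/M list, genes of mitosis, in JEG3 3 rose and 22 fell of 36 tested (3 and 24 adjusted over the list alone), with falls of the phosphatase CDC25B (-0.89), the cytokinesis protein ANLN (-0.82), the centromere protein CENPF (-0.53) and GTSE1 (-0.66). In BeWo 6 rose and 5 fell (6 and 5 adjusted over the list alone). Camera gave adjusted p = 8.78e-05 in JEG3, adjusted p = 0.0976 with an estimated correlation, and 0.573 in BeWo. Of the S-phase list, in BeWo 9 rose and 5 fell of 35 tested (12 and 5 adjusted over the list alone) and in JEG3 8 rose and 9 fell (8 and 10 adjusted over the list alone). The ribonucleotide reductase subunit RRM2 (0.74 in BeWo, 0.63 in JEG3) and the cyclin CCNE1 (0.35 and 0.56) rose, the helicase subunit MCM3 fell (-0.41 and -0.70), and CDT1 rose in JEG3 (0.59). The camera test gave adjusted p = 0.0381 in BeWo (adjusted p = 0.532 with an estimated correlation, and 0.0533 without BeWo mimic replicate 2) and 0.833 in JEG3. Of the p53 targets, in BeWo 7 rose and 3 fell of 27 tested (8 and 3 adjusted over the list alone) and in JEG3 8 rose and 4 fell (10 and 5 adjusted over the list alone). MDM2 rose by 0.41 and 0.75 and SESN1 by 0.55 and 0.42, while the membrane protein PERP fell (-0.48 and -0.69). With camera the list had adjusted p = 0.0461 and 0.0407, and adjusted p = 0.532 and 0.324 with an estimated correlation. The BeWo call was lost by fry (0.0518) and without BeWo control replicate 1 (0.0827), BeWo mimic replicate 1 (0.0796) or any of the 4 JEG3 libraries (0.0517 to 0.0573), and the JEG3 call without JEG3 mimic replicate 1 (0.103) or 2 (0.058).

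Several further lists were called in JEG3. Of the hypoxia and glycolysis genes, in JEG3 17 rose and 2 fell of 32 tested (18 and 6 adjusted over the list alone) and in BeWo 9 rose and 7 fell (10 and 9 adjusted over the list alone). Adrenomedullin ADM rose by 0.98, NDRG1 by 1.09, the vascular growth factor VEGFA by 0.73 and the glucose transporter SLC2A3 by 0.14 in JEG3, while SLC2A3 fell by 0.49 in BeWo. Camera gave adjusted p = 8.78e-05 in JEG3 (adjusted p = 0.194 with an estimated correlation) and 0.447 in BeWo. Of the extravillous trophoblast genes, markers of the invasive trophoblast, in JEG3 9 rose and 4 fell of 23 tested (10 and 5 adjusted over the list alone) and in BeWo 3 rose and 7 fell (4 and 8 adjusted over the list alone). MMP2 and the death ligand TNFSF10 (1.04) rose in JEG3, as did the cytokine subunit EBI3 (1.25), while fibronectin FN1 fell in JEG3 (-0.47) and BeWo (-1.19). The camera test gave adjusted p = 0.024 in JEG3 (adjusted p = 0.324 with an estimated correlation, and 0.0658 without JEG3 mimic replicate 1) and 0.843 in BeWo. Of the NF-kappaB response genes, in JEG3 8 rose and 2 fell of 20 tested (8 and 2 adjusted over the list alone) and in BeWo 3 rose and 3 fell (3 and 3 adjusted over the list alone). IER3 (0.98), the inhibitor NFKBIA (0.71) and TNF, from 0.0427 ± 0.0603 to 1.48 ± 0.262 TPM, rose in JEG3. TNIP1, the reported target with an 8mer site, is also on this list and fell in both lines. With camera the list had adjusted p = 0.024 in JEG3 (adjusted p = 0.281 with an estimated correlation, and 0.0631 with size factors) and 0.7 in BeWo. SLC2A3 in JEG3 lost its call without JEG3 control replicate 2 (adjusted p = 0.0616), JEG3 mimic replicate 1 (0.096) or JEG3 mimic replicate 2 (0.0899), and without mitochondrial genes (0.0774).

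Of the MAPK feedback genes, in JEG3 9 rose and 3 fell of 23 tested (9 and 4 adjusted over the list alone) and in BeWo 3 rose and 5 fell (4 and 5 adjusted over the list alone). The phosphatase DUSP5 (1.30) and the AP-1 genes JUNB (1.08) and FOS (0.31) rose in JEG3, and FOS fell in BeWo (-0.57). Camera gave adjusted p = 0.0409 in JEG3 (adjusted p = 0.324 with an estimated correlation) and 0.878 in BeWo. The JEG3 call was lost with size factors (0.0984) and without BeWo mimic replicate 2 (0.0529), JEG3 control replicate 2 (0.0857) or JEG3 mimic replicate 2 (0.0543). Of the sterol synthesis genes, in JEG3 9 rose and 2 fell of 29 tested (9 and 2 adjusted over the list alone) and in BeWo 8 rose and 2 fell (9 and 4 adjusted over the list alone). MSMO1 (0.68), the reductase HMGCR (0.69) and the synthase HMGCS1 (0.53) rose in JEG3, and the kinase PMVK fell (-0.73). The camera test gave adjusted p = 0.0153 in JEG3 (adjusted p = 0.324 with an estimated correlation, and 0.0849 without JEG3 control replicate 2) and 0.136 in BeWo. Of the replication-dependent histones, whose RNAs lack a poly(A) tail, in JEG3 4 rose and 0 fell of 16 tested (3 and 0 adjusted over the list alone) and in BeWo 4 rose and 1 fell (4 and 1 adjusted over the list alone). H2BC4 (0.69), H2BC5 (0.45) and H4C8 (0.67) rose in JEG3, and H2BC9 fell in BeWo (-0.74). With camera the list had adjusted p = 0.00486 in JEG3 (adjusted p = 0.281 with an estimated correlation) and 0.0684 in BeWo, and these near-identical genes are uncertain for shared reads. FOS in JEG3 lost its call without JEG3 control replicate 1 (adjusted p = 0.0809), JEG3 control replicate 2 (0.0604), JEG3 mimic replicate 1 (0.11) or JEG3 mimic replicate 2 (0.0682). H2BC4 in JEG3 lost its call without JEG3 control replicate 1 (adjusted p = 0.0809), JEG3 mimic replicate 1 (0.0669) or JEG3 mimic replicate 2 (0.0585), and with pseudocount 0.1 (0.104). H2BC5 in JEG3 lost its call without JEG3 control replicate 2 (adjusted p = 0.132), JEG3 mimic replicate 1 (0.128) or JEG3 mimic replicate 2 (0.0782). H4C8 in JEG3 lost its call without JEG3 mimic replicate 2 (adjusted p = 0.0628), and with pseudocount 0.1 (0.0972). H2BC9 in BeWo lost its call without BeWo control replicate 1 (adjusted p = 0.0582), and with pseudocount 0.1 (0.0767).

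No other list passed by camera in either line, and the camera values follow for BeWo and JEG3 in turn. Fry, which asks whether genes of a list move on balance one way and does not compare them with other genes, gave calls where camera gave none. In BeWo these were the adhesion (adjusted p = 0.00743), imprinted (0.00894), steroidogenesis (0.0297) and extravillous (0.0342) lists. In JEG3 they were the adhesion (0.00458), imprinted (0.00599), steroidogenesis (0.0182), interferon (0.0211), S-phase (0.0277), YAP (0.0306), angiogenic (0.0467) and fibroblast (0.0467) lists. Of cytotrophoblast genes, in BeWo 5 rose and 11 fell of 29 tested (8 and 12 adjusted over the list alone) and in JEG3 8 rose and 11 fell (8 and 12 adjusted over the list alone), at adjusted p = 0.895 and 0.917. PEG10 (-0.44 and -1.61) and the stem cell factor TP63 (-0.47 and -1.22) fell and the keratin KRT18 (0.42 and 0.68) and GATA2 (0.20 and 0.72) rose. Of interferon response genes, in BeWo 2 rose and 7 fell of 29 tested (2 and 7 adjusted over the list alone) and in JEG3 0 rose and 9 fell (0 and 9 adjusted over the list alone), at adjusted p = 0.878 and 0.143. STAT1 (-0.44 and -0.49) and the RNA sensor DDX58 (-0.54 and -0.78) fell in both lines, IFI6 (-0.84) and HERC5 (-0.64) in JEG3. Of imprinted genes, in BeWo 1 rose and 8 fell of 19 tested (1 and 9 adjusted over the list alone) and in JEG3 1 rose and 6 fell (1 and 7 adjusted over the list alone), at adjusted p = 0.0684 and 0.324. IGF2 fell in both lines (by 1.17 in JEG3), the receptor IGF2R fell in BeWo (-0.75) and NLRP2 rose (0.73 and 0.77). Of adhesion and epithelial-mesenchymal transition genes, in BeWo 3 rose and 8 fell of 23 tested (3 and 10 adjusted over the list alone) and in JEG3 4 rose and 10 fell (4 and 11 adjusted over the list alone), at adjusted p = 0.136 and 0.238. The galectin LGALS1 fell in both (-0.87 and -1.17), the tight junction protein TJP1 by 1.10 in BeWo and the integrin ITGB5 by 0.88 in JEG3. Of steroidogenesis genes, in BeWo 5 rose and 2 fell of 14 tested (5 and 2 adjusted over the list alone) and in JEG3 4 rose and 2 fell (4 and 2 adjusted over the list alone), at adjusted p = 0.205 and 0.162. HSD3B1 rose (1.08 and 0.86), POR fell (-0.82 and -0.29) and CYP11A1 changed by -0.19 and 0.49. PEG10 in BeWo lost its call without BeWo control replicate 1 (adjusted p = 0.0574). TP63 in BeWo lost its call without BeWo control replicate 1 (adjusted p = 0.0964), BeWo control replicate 2 (0.0728), BeWo mimic replicate 1 (0.0891) or BeWo mimic replicate 2 (0.057). GATA2 in BeWo lost its call without BeWo control replicate 1 (adjusted p = 0.103), BeWo control replicate 2 (0.0934) or BeWo mimic replicate 1 (0.117), and without a filter (0.0542). DDX58 in BeWo lost its call without BeWo control replicate 1 (adjusted p = 0.0768), BeWo control replicate 2 (0.131) or BeWo mimic replicate 1 (0.12). POR in JEG3 lost its call without JEG3 mimic replicate 2 (adjusted p = 0.0599). CYP11A1 in BeWo lost its call without BeWo control replicate 1 (adjusted p = 0.0826), BeWo control replicate 2 (0.122) or BeWo mimic replicate 2 (0.0936), and with size factors (0.116) and without mitochondrial genes (0.0513).

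Of apoptosis regulators, in BeWo 4 rose and 4 fell of 29 tested (4 and 4 adjusted over the list alone) and in JEG3 5 rose and 6 fell (6 and 8 adjusted over the list alone), at adjusted p = 0.779 and 0.917. MCL1 rose (0.60 and 0.62), BMF (-1.05 and -1.20) and the cytochrome c gene CYCS (-0.37 and -0.60) fell, and PMAIP1 rose in JEG3 (1.42). Of TGF-beta targets, in BeWo 3 rose and 3 fell of 22 tested (3 and 3 adjusted over the list alone) and in JEG3 6 rose and 4 fell (7 and 4 adjusted over the list alone), at adjusted p = 0.843 and 0.314. ID2 rose (0.61 and 0.93), ID1 fell (-1.06 and -1.42) and SERPINE1 rose in JEG3 (0.82). Of YAP targets, in BeWo 1 rose and 3 fell of 18 tested (1 and 3 adjusted over the list alone) and in JEG3 1 rose and 6 fell (1 and 6 adjusted over the list alone), at adjusted p = 0.779 and 0.358, with falls of MYOF (-0.58 and -0.25). Of angiogenic factors, in BeWo 5 rose and 3 fell of 13 tested (5 and 3 adjusted over the list alone) and in JEG3 4 rose and 2 fell (4 and 2 adjusted over the list alone), at adjusted p = 0.136 and 0.203, with SERPINF1 falling (-0.28 and -0.73). Of the microRNA machinery, in BeWo 5 rose and 3 fell of 26 tested (5 and 3 adjusted over the list alone) and in JEG3 6 rose and 4 fell (7 and 5 adjusted over the list alone), at adjusted p = 0.0684 and 0.138. LIN28A (1.30 and 0.47) and the deadenylase subunits CNOT6 (0.63 and 0.50) and CNOT7 (0.57 and 0.36) rose. Among markers of other cells, fibroblast genes gave 1 rise and 1 fall in BeWo and 1 fall in JEG3 of 5 tested (the same counts adjusted over the list alone), at adjusted p = 0.843 and 0.359. Leukocyte genes gave 1 rise and 1 fall in BeWo and 2 rises and 1 fall in JEG3 of 6 (again the same counts adjusted over the list alone), at adjusted p = 0.779 and 0.433, with CD68 rising and CSF1R falling (-0.71 and -1.21). Of 3 endothelial genes CDH5 fell (-0.78 and -0.31), EGFL7 changed by -0.51 and 0.45, and ESAM fell in BeWo (-0.62), and adjusted over the list alone all 3 passed in each line. Of 3 carcinoma epithelial genes SFN rose (0.47 and 0.90) and APOA2 rose in JEG3 (1.10), and adjusted over the list alone 2 passed in each line. MYOF in JEG3 lost its call without JEG3 control replicate 1 (adjusted p = 0.178), JEG3 mimic replicate 1 (0.107) or JEG3 mimic replicate 2 (0.139), and with size factors (0.129) and without a filter (0.067). SERPINF1 in BeWo lost its call without BeWo control replicate 1 (adjusted p = 0.0609), BeWo control replicate 2 (0.136) or BeWo mimic replicate 2 (0.133), and with size factors (0.0669) and without a filter (0.0558). CDH5 in JEG3 lost its call without JEG3 control replicate 1 (adjusted p = 0.132), JEG3 mimic replicate 1 (0.106) or JEG3 mimic replicate 2 (0.0874), and with size factors (0.06). EGFL7 in BeWo lost its call without BeWo control replicate 1 (adjusted p = 0.0847), BeWo control replicate 2 (0.0963) or BeWo mimic replicate 2 (0.116), and without a filter (0.0524). EGFL7 in JEG3 lost its call without JEG3 control replicate 1 (adjusted p = 0.131), JEG3 mimic replicate 1 (0.128) or JEG3 mimic replicate 2 (0.0673), and without a filter (0.0664) and with the libraries of that line alone (0.0667). ESAM in BeWo lost its call without BeWo control replicate 1 (adjusted p = 0.11) or BeWo mimic replicate 2 (0.102). SFN in BeWo lost its call without BeWo control replicate 1 (adjusted p = 0.0546) or BeWo mimic replicate 1 (0.0513). APOA2 in JEG3 lost its call without JEG3 control replicate 2 (adjusted p = 0.0528) or JEG3 mimic replicate 1 (0.0562).

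**Figure D3:**
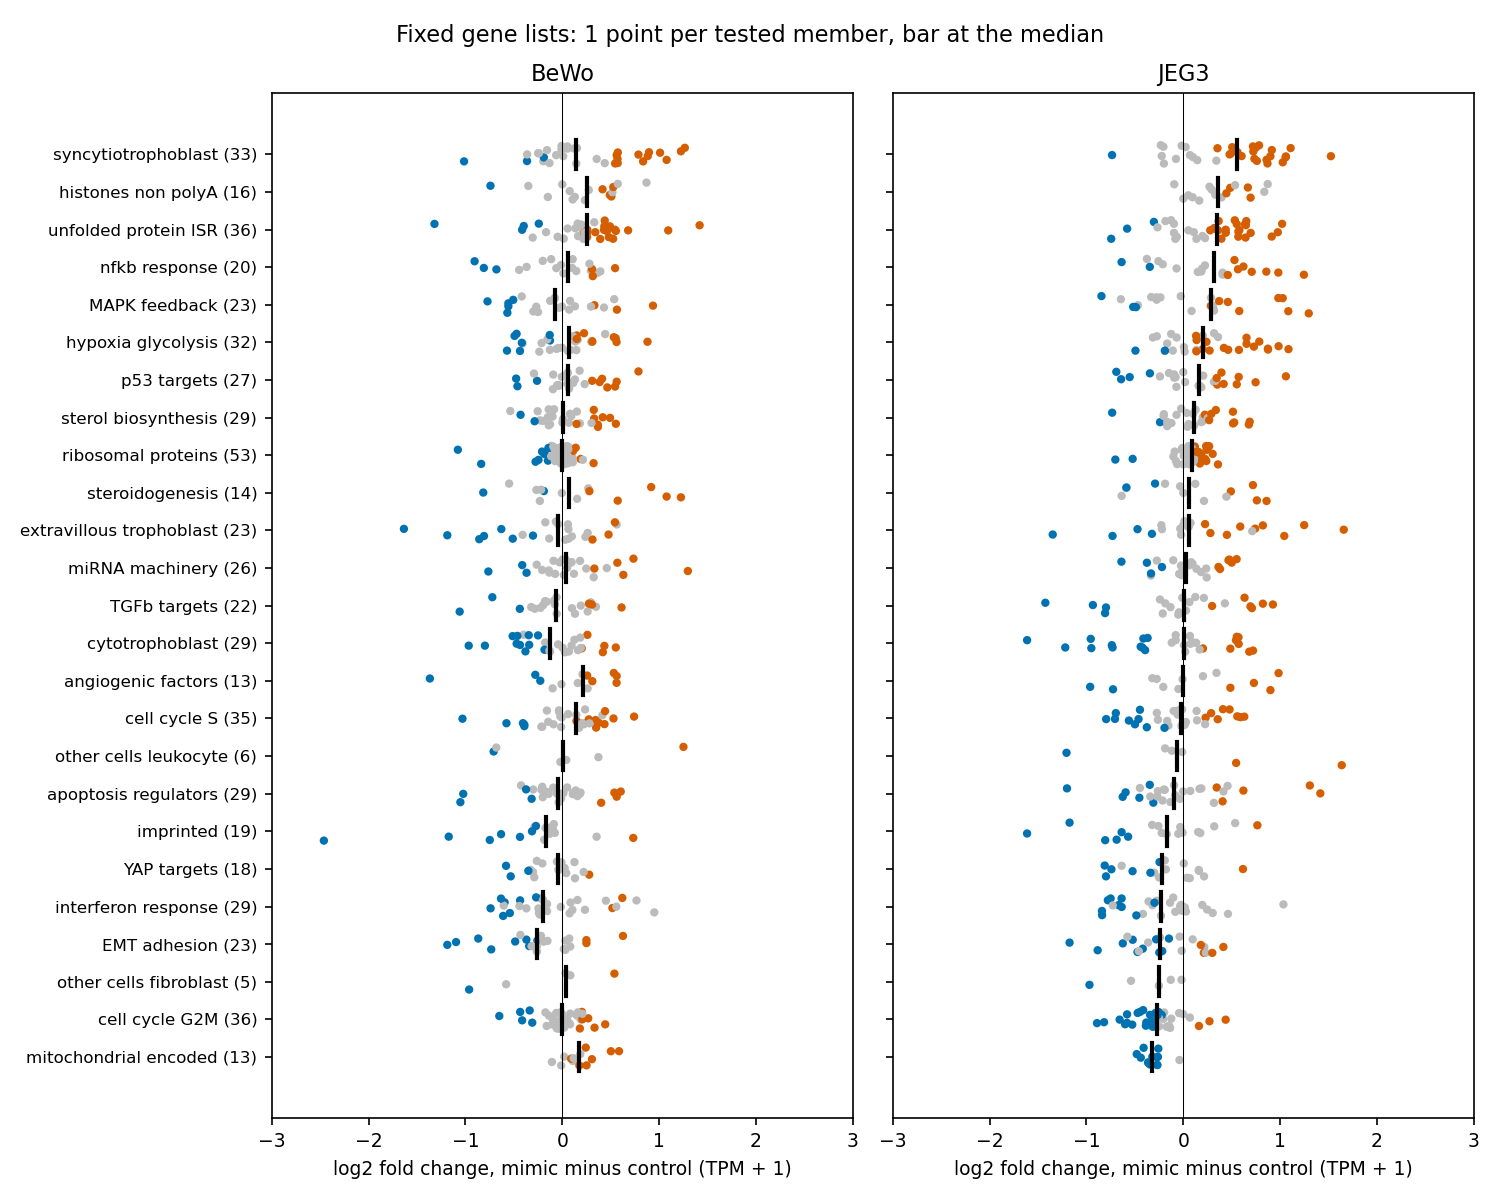
Log2 fold change of TPM + 1 (horizontal axis) of the tested members of 25 gene lists (rows) in BeWo and JEG3. Each point is 1 gene, orange where it rose, blue where it fell and grey where it did not pass, and the bar is the list median. In the syncytiotrophoblast list 13 points are orange and 3 blue in BeWo, and 21 are orange and 1 blue in JEG3.

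The camera test compares the mean of variance-scaled statistics of a list with that of all other genes. Its direction can therefore differ from the sign of a list's own median. The median change of all genes was -0.061 in BeWo and -0.066 in JEG3. This offset does not account for every case. The medians of the MAPK feedback (-0.077) and TGF-beta (-0.067) lists in BeWo and the apoptosis list (-0.096) in JEG3 lay below it. In BeWo the apoptosis, G2/M, MAPK feedback and TGF-beta lists had a median and mean below 0 and a test direction of up. The NF-kappaB, fibroblast and ribosomal lists in BeWo had a median above and a mean below 0, also with a direction of up. In JEG3 the apoptosis and S-phase lists had a median and mean below 0 and a direction of up. The angiogenic and leukocyte lists there had a median below and a mean above 0, and the cytotrophoblast list the reverse, each with a direction of up. With size factors the sign of the median turned for the apoptosis, G2/M and extravillous lists in BeWo, and for the angiogenic and S-phase lists in JEG3. Without mitochondrial genes it turned for the G2/M list in BeWo, and for the TGF-beta, cytotrophoblast, microRNA machinery and steroidogenesis lists in JEG3.

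The difference of the mimic's effect between the lines was tested directly, as JEG3 minus BeWo. COL6A3 (difference 2.11 ± 0.20, adjusted p = 0.00283) and IFITM1 (1.81 ± 0.13, adjusted p = 0.00165) fell in BeWo and stood at changes of 0.068 and -0.0077 in JEG3. The neuronal tubulin TUBB3 fell in BeWo (-0.47) and rose in JEG3 (1.17), as did the calcium-binding protein CALB2 (-1.01 and 0.77). NPPB, ANKRD23, the riboflavin transporter SLC52A3 (1.34 in JEG3) and PIP5KL1 (0.95) also had a higher effect in JEG3. COL5A1 and VAV3 were low in BeWo, COL5A1 at 0.0280 TPM in control and 0.0147 TPM in mimic libraries and VAV3 at 1.18 and 1.15 TPM, so the difference of COL5A1 came from JEG3 alone. On the other side, the guanine nucleotide exchange factor VAV3 (-1.59), FMC1 (-1.40) and the interleukin receptor IL17RE (-1.14) fell in JEG3 and had changes of -0.0083, 0.32 and 0.42 in BeWo. The antiviral MX1 changed by 0.77 in BeWo and -0.73 in JEG3, passing in neither line (difference -1.49 ± 0.39, adjusted p = 0.0499). EIF3CL, HSPE1-MOB4, RNA5SP268, RNA5SP217, RNA5SP18, RPL39P36 and TMEM183B were also among the largest differences and are uncertain for shared reads. MX1 lost its difference call whichever library was left out (adjusted p 0.0555 to 0.145), and with size factors (0.0506), without a filter (0.128) and with pseudocount 0.1 (0.0553). VAV3 lost its difference call whichever library was left out (adjusted p 0.0503 to 0.0978), and without a filter (0.0899) and with pseudocount 0.1 (0.0855). FMC1 lost its difference call whichever library was left out, except BeWo control replicate 2 (adjusted p 0.0542 to 0.104), and without a filter (0.0964). IL17RE lost its difference call whichever library was left out, except JEG3 control replicate 2 or JEG3 mimic replicate 1 (adjusted p 0.0591 to 0.0905), and without a filter (0.0846). PIP5KL1 lost its difference call without BeWo control replicate 1 (adjusted p = 0.0721), BeWo control replicate 2 (0.0766), BeWo mimic replicate 2 (0.0738), JEG3 mimic replicate 1 (0.0697) or JEG3 mimic replicate 2 (0.075), and without a filter (0.0684). CALB2 lost its difference call without BeWo control replicate 2 (adjusted p = 0.0519).

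In all, 663 genes had a higher and 554 a lower effect in JEG3, 1217 of 13553. The count was 392 without a filter on low values, and with mitochondrial genes removed the split was 484 and 927. With any single library left out the total was lower, by an amount that depended on the library. Among the lists, lower effects in JEG3 were found for mitochondrially encoded RNAs (0 higher and 12 lower of 13, 0 and 13 adjusted over the list alone, median difference -0.45, adjusted p = 7.06e-13, and adjusted p = 0.177 with an estimated correlation) and G2/M genes (0 higher and 7 lower of 36, 0 and 16 adjusted over the list alone, median difference -0.24, adjusted p = 6.69e-08, and adjusted p = 0.0617 with an estimated correlation). Higher effects were found for hypoxia and glycolysis genes (11 higher and 0 lower of 32, 15 and 2 adjusted over the list alone, median difference 0.15, adjusted p = 0.000117, and adjusted p = 0.177 with an estimated correlation), extravillous trophoblast genes (11 higher and 1 lower of 23, 12 and 1 adjusted over the list alone, median difference 0.48, adjusted p = 0.000171, and adjusted p = 0.177 with an estimated correlation) and ribosomal protein genes (9 higher and 0 lower of 53, 12 and 1 adjusted over the list alone, median difference 0.089, adjusted p = 3.85e-07, and adjusted p = 0.575 with an estimated correlation). The same held for NF-kappaB response genes (1 higher and 0 lower of 20, 3 and 0 adjusted over the list alone, median difference 0.33, adjusted p = 0.0102, and adjusted p = 0.177 with an estimated correlation), MAPK feedback genes (4 higher and 0 lower of 23, 7 and 2 adjusted over the list alone, median difference 0.27, adjusted p = 0.0232, and adjusted p = 0.315 with an estimated correlation) and syncytiotrophoblast genes (8 higher and 3 lower of 33, 11 and 4 adjusted over the list alone, median difference 0.15, adjusted p = 0.0249, and adjusted p = 0.305 with an estimated correlation). Of these 6 lists the ribosomal call was lost by fry (adjusted p = 0.139), the NF-kappaB call without BeWo control replicate 1 (0.0629), the MAPK call without BeWo control replicate 1 (0.0586), BeWo mimic replicate 1 (0.0593) or JEG3 control replicate 2 (0.0777), and the syncytiotrophoblast call without BeWo control replicate 2 (0.0659), JEG3 control replicate 1 (0.0936) or JEG3 mimic replicate 2 (0.115). The other 17 lists did not pass by camera, and of these fry called the S-phase list (adjusted p = 0.0195). In the difference the apoptosis list had a median and mean above 0 and a direction of down, and the cytotrophoblast and adhesion lists had medians and means of opposite sign.

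**Figure D4:**
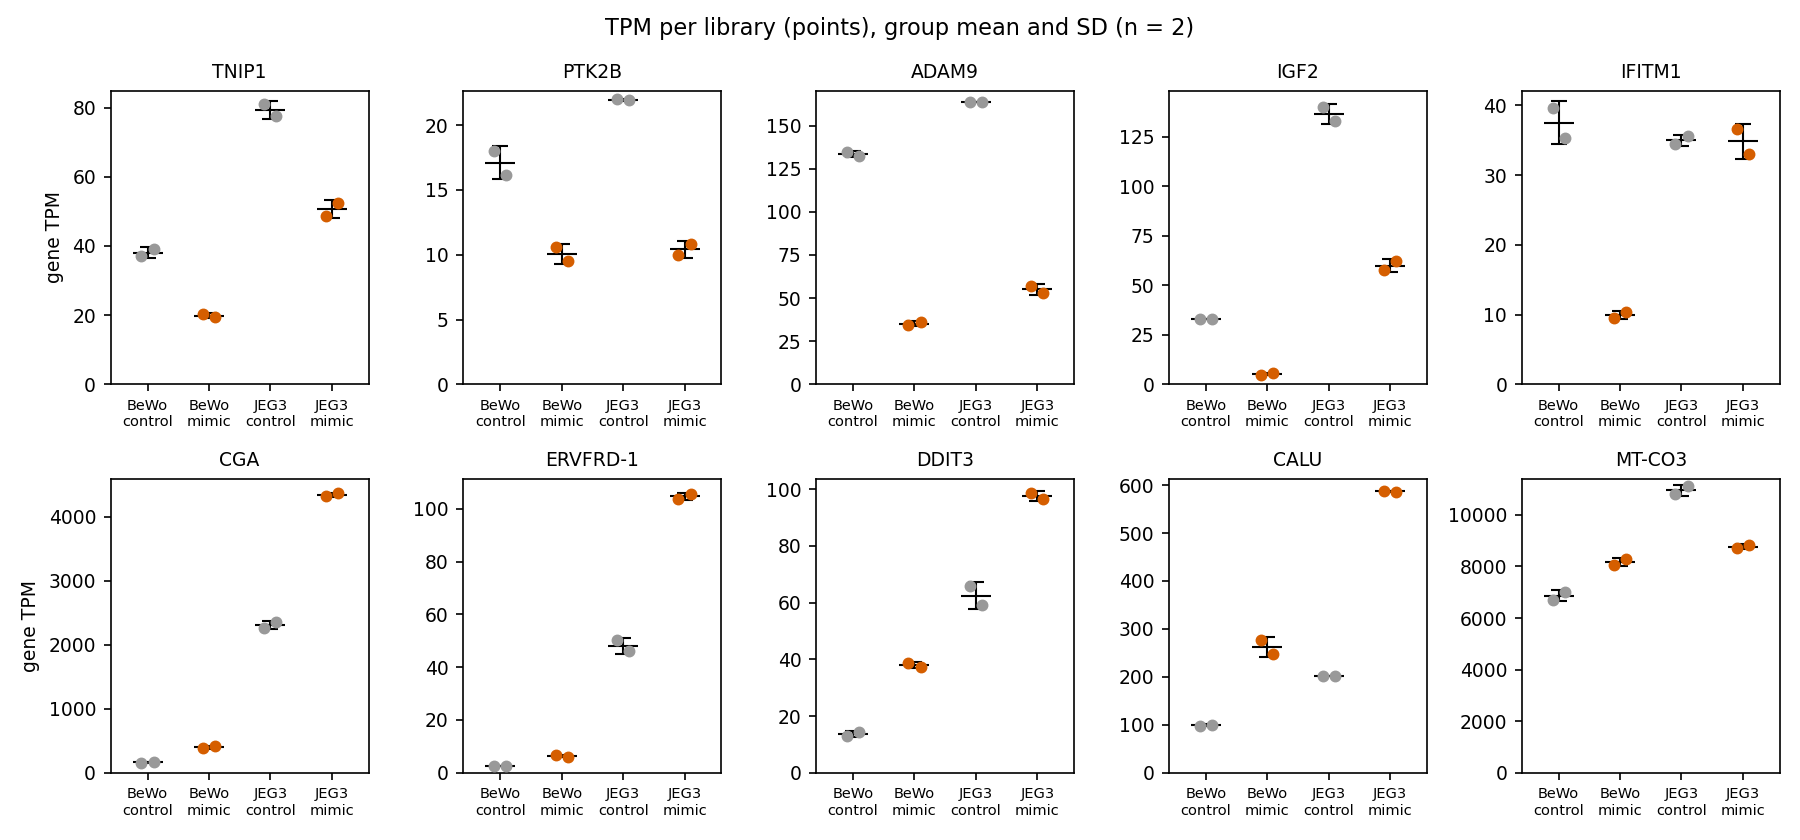
TPM of 10 genes (vertical axes) in the 4 groups (horizontal axis). Points are single libraries, and bars give the mean and SD of 2 libraries; ADAM9 and IGF2 are lower with the mimic in both lines, CGA and CALU higher, and IFITM1 lower in BeWo.

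The control libraries of the lines were compared to give the background difference, as JEG3 minus BeWo. HLA-G, the trophoblast class I antigen, stood at 150.1 ± 3.6 TPM in JEG3 and 0.0630 ± 0.0224 TPM in BeWo, and aromatase CYP19A1 at 233 ± 28.6 and 5.08 ± 0.0712 TPM. Thymosin TMSB4X (439.5 ± 21 against 0.607 ± 0.625 TPM), the fatty acid-binding FABP5 (295 ± 16.6 against 0.568 ± 0.351), the cancer-testis antigen MAGEA4 (6.65), the lysyl hydroxylase PLOD2 (6.43), the amino acid transporters SLC6A19 (5.72) and SLC38A1 (5.37) and TUSC3 (5.53) were also higher in JEG3. The glutathione transferase MGST1 (389.5 ± 12.7 TPM in BeWo against 2.73 ± 1.05 in JEG3), the testis-specific bromodomain gene BRDT (-6.25), the antigen PRAME (-6.09), NME4 (-5.58), MDFI (-5.50), L1TD1 (-5.42), RNF5 (-5.40) and the calcium channel ITPR3 (-5.35) were lower in JEG3. PODXL2 was listed at 0 in both JEG3 control libraries and at 42.2 TPM in BeWo, and the pseudogenes SSXP10 and IGHVII-44-2 are uncertain. All these differences passed, and in total 4254 genes were higher and 4484 lower in JEG3 (64.5% of genes).

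By camera, JEG3 control libraries were higher for syncytiotrophoblast genes (27 higher and 2 lower of 33, 27 and 2 adjusted over the list alone, adjusted p = 6.89e-10, and adjusted p = 0.0934 with an estimated correlation), stress response genes (26 higher and 8 lower of 36, 27 and 8 adjusted over the list alone, adjusted p = 4.57e-05, and adjusted p = 0.361 with an estimated correlation) and histones (14 higher and 1 lower of 16, 15 and 1 adjusted over the list alone, adjusted p = 7.16e-05, and adjusted p = 0.158 with an estimated correlation). They were also higher for S-phase genes (26 higher and 1 lower of 35, 26 and 1 adjusted over the list alone, adjusted p = 0.000103, and adjusted p = 0.135 with an estimated correlation), extravillous trophoblast genes (15 higher and 3 lower of 23, 15 and 3 adjusted over the list alone, adjusted p = 0.000145, and adjusted p = 0.158 with an estimated correlation), sterol synthesis genes (18 higher and 1 lower of 29, 18 and 1 adjusted over the list alone, adjusted p = 0.000515, and adjusted p = 0.262 with an estimated correlation) and MAPK feedback genes (15 higher and 3 lower of 23, 16 and 3 adjusted over the list alone, adjusted p = 0.00161, and adjusted p = 0.262 with an estimated correlation). Lower values were found for ribosomal protein genes (4 higher and 43 lower of 53, 4 and 44 adjusted over the list alone, adjusted p = 1.16e-09, and adjusted p = 0.398 with an estimated correlation). The other 17 lists did not pass by camera, and fry called 12 of them.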

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

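Tests chosen only after the result was seen were those of site strength for the seed sites and of a single library, a length bias and a line response for the mitochondrial RNAs. The other tests below were fixed before their own results were seen, but after the patterns they bear on.

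Of 249 genes with a 3' UTR seed site 117 fell and 3 rose in BeWo and 100 fell and 11 rose in JEG3, and the line differences (JEG3 minus BeWo) of genes with a site had a median 0.10 above that of genes without one (camera p = 0.0227, and p = 0.209 with an estimated correlation). Base composition and CpG content were argued against, since 0 of 299 control 7-mers gave a shift as low in either line (lowest -0.222 in BeWo and -0.129 in JEG3). Length of the 3' UTR and expression level were argued against too, since against matched genes the shift averaged over the lines was -0.294. The 8mer median minus the 6mer median was -0.262 on average, which goes with direct repression through the seed as a hypothesis. The 8mer and 7mer medians differed by less than the SE of the 8mer median in each line, so their order was not resolved. Whether the line difference has a biological cause stays open and was not tested.

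Of 13 mitochondrially encoded RNAs 7 rose and 0 fell in BeWo (list call lost by fry, adjusted p = 0.0515, and with an estimated correlation, adjusted p = 0.57), 0 rose and 12 fell in JEG3 (adjusted p = 0.324 with an estimated correlation), and the median difference was -0.45 (camera adjusted p = 7.06e-13, and adjusted p = 0.177 with an estimated correlation). A single deviating library was argued against, because the median difference stayed between -0.536 and -0.38 whichever library was left out. A length bias shared by transcripts of up to 1812 bases, the longest of these RNAs, was argued against as the whole cause. The 3603 nuclear coding genes with transcripts up to that length differed by a median of -0.047 (SE 0.00609). Genes as short as the shorter of these RNAs were not taken apart, so a bias confined to such lengths was not tested. A line difference in the response to the mimic and a difference between library preparations cannot be told apart for the -0.454 of these RNAs, since the labels name no batch. Among these RNAs the differences were -0.57 for MT-CO3, -0.36 for MT-ND1, -0.35 for MT-ND3 and -0.53 for MT-ND6.

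Of 33 syncytiotrophoblast genes 13 rose and 3 fell in BeWo (median 0.145, 0.096 without BeWo control replicate 1 and 0.554 at 10 TPM or more, and adjusted p = 0.51 with an estimated correlation), 21 rose and 1 fell in JEG3 (median 0.56, adjusted p = 0.0976 with an estimated correlation), and the median difference was 0.15 (camera adjusted p = 0.0249, and adjusted p = 0.305 with an estimated correlation). With the trend on GC content, length and expression removed, the median averaged over the lines was 0.38 (SE 0.127), against 0.352 before, so that trend was argued against as the whole cause. Without the families of near-identical genes it was 0.654 (SE 0.129), and with median-ratio size factors 0.43 (SE 0.142), which argues against shared reads and against a shift of all genes. A biological response of the cells to the mimic remains a hypothesis, which none of these checks tested. Single genes of the list differed by -0.35 for CGA, -0.47 for HSD17B1 and 0.34 for PGF.

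All further differences are JEG3 effect minus BeWo effect on the log2(TPM + 1) scale, and each passed a test of the difference itself, by limma for genes and by camera with the preset correlation for lists. By list, the median difference was -0.24 for G2/M genes, 0.48 for extravillous trophoblast genes, 0.15 for hypoxia and glycolysis genes and 0.27 for MAPK feedback genes. With an estimated correlation these 4 calls were lost, at adjusted p = 0.0617, 0.177, 0.177 and 0.315 in the same order. The median difference was 0.33 for NF-kappaB response genes and 0.09 for ribosomal protein genes, with calls lost at adjusted p = 0.177 and 0.575 with an estimated correlation. The ribosomal call was also lost by fry (adjusted p = 0.139), the NF-kappaB call without BeWo control replicate 1 (0.0629), and the MAPK call without BeWo control replicate 1 (0.0586), BeWo mimic replicate 1 (0.0593) or JEG3 control replicate 2 (0.0777).

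Effects higher in JEG3 than in BeWo gave differences of 2.14 for ANKRD23, 2.11 for COL6A3, 2.0 for NPPB, 1.81 for IFITM1, 1.78 for CALB2, 1.69 for SLC52A3, 1.64 for TUBB3, 1.6 for PIP5KL1, 1.58 for COL5A1, 1.43 for PMAIP1, 1.29 for IGF2 and 1.15 for EBI3. Smaller positive differences were 1.11 for MMP2, 0.98 for SDC1, 0.97 for EGFL7, 0.96 for DUSP5, 0.95 for JUNB, 0.95 for LATS2, 0.88 for FOS, 0.82 for TJP1, 0.79 for NDRG1, 0.71 for FN1, 0.69 for IER3 and 0.68 for CYP11A1. Positive differences further down were 0.63 for SLC2A3, 0.62 for TBC1D1, 0.58 for SLC7A5, 0.57 for TNFSF10, 0.56 for SERPINE1, 0.52 for GATA2, 0.52 for POR, 0.50 for LCP1, 0.49 for IGF2R, 0.47 for CDH5, 0.45 for CDT1 and 0.45 for ADM. The remaining positive differences were 0.45 for HMGCS1, 0.42 for VEGFA, 0.38 for LIN28B, 0.38 for RPLP1, 0.36 for TGFBR3, 0.31 for RPL7A, 0.27 for RPL3, 0.26 for KRT18 and 0.17 for RPL11. COL5A1 stood at 0.0280 TPM in control and 0.0147 TPM in mimic libraries of BeWo, so its difference came from JEG3 alone.

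Lower in JEG3, the differences were -1.72 for FMC1, -1.58 for VAV3, -1.56 for IL17RE, -1.49 for MX1, -1.18 for PEG10, -0.95 for STEAP3, -0.94 for IFI6, -0.92 for RCOR2, -0.83 for LIN28A, -0.82 for DNAI1, -0.79 for CRAT and -0.79 for COL1A1. Smaller negative differences were -0.78 for DDIT3, -0.78 for ARHGEF17, -0.75 for TP63, -0.69 for ITGB5, -0.65 for GTSE1, -0.48 for PMVK, -0.47 for CENPF, -0.45 for SERPINF1 and -0.29 for MCM3. The adjusted p of these differences ran up to 0.0499 for MX1.

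Differences that are uncertain for reads shared with near-identical genes were 3.36 for RNA5SP217, -2.59 for RNA5SP18, -1.84 for RNA5SP268, -2.04 for RPL39P36, -1.82 for TMEM183B, -2.11 for EIF3CL and -1.51 for HSPE1-MOB4. RNA5SP217, RNA5SP18 and TMEM183B were listed at 0 in 1 group, so their values are no folds.

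Transcripts without a gene symbol were outside the main comparisons. Of 1041 such transcripts tested, 4 changed in BeWo (3 up and 1 down) and 11 in JEG3 (5 up and 6 down).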

How the results depend on the processing

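The tests that needed read counts, DESeq2 and limma-voom, were planned but not run, because the values are TPM. The pseudocounts of 0.1 and 5 and the removal of mitochondrial genes were chosen after seeing the data. The seed site shift kept its direction in 20 of 20 alternatives in each line, and the counts of genes changed in JEG3, on average and between the control lines stayed within 1.5 times in 17 of 17, though the rises in JEG3 alone went from 1883 to 1208 without JEG3 mimic replicate 1. Genes changed in BeWo numbered 2242 to 3891 with 1 library left out. Genes whose effect differed between the lines numbered 392 without a filter and 247 to 743 with 1 library left out, against 1217, and genes changed the same way 1359 to 1839 against 2130. A left-out library leaves fewer samples in these fits, and the cause of the lower count without a filter was not tested. The correlation between the lines was 0.43 without a filter, 0.606 at 10 TPM or more, 0.538 for protein-coding genes, 0.373 and 0.568 with pseudocounts 0.1 and 5, 0.47 without mitochondrial genes, 0.553 with each line fitted alone and 0.429 to 0.457 with 1 library left out. The cause of these moves was not tested. With an estimated correlation 0 lists passed in BeWo, 0 in JEG3 and 0 for the line difference, and fry, which tests another hypothesis, called 19 in JEG3. Libraries with the same replicate number did not deviate together (correlation -0.029 in BeWo and 0.024 in JEG3), so the numbers were not taken to pair them. With a replicate block 287 genes differed between the lines, no other count moved by over 1.5 times, and of the list calls the MAPK list in JEG3 was lost (adjusted p = 0.0535) and the histone list in BeWo gained (0.0456). Of 292 called values of named genes, none reversed in a fit without 1 library, and those listed next lost the call in at least 1 such fit. Most named genes were picked from these same data by size of change or adjusted p. For the largest changes within a line, both mimic libraries already lay on 1 side of both controls, so no reversal could occur there. Over all calls of a line, a smaller share than of the named ones held without 1 of its own libraries. Lost in 6 or more of 8 fits were TNF, H2BC4, H2BC5, MT-ND1 in BeWo, TJP1 in JEG3 and MX1, VAV3, FMC1, TMEM183B, HSPE1-MOB4, IL17RE, RNA5SP18 for the difference. Lost in fewer fits were NFKBIA, TP63, CYP11A1, DDX58, DUSP5, EGFL7, FAP, GATA2, SERPINF1, TARS3, VEGFA, ANLN, ESAM, NME1-NME2, SDC1, SFN, COL1A1, H2BC9, PEG10, TGFBR3 in BeWo, FOS, H2AW, CDH5, EGFL7, GAST, H2BC4, H2BC5, MYOF, PTPMT1, RDM1P4, SLC2A3, APOA2, LUM, PRKG1, H4C8, POR in JEG3 and PIP5KL1, RPL39P36, CALB2 for the difference. Size factors ended 8 calls of named genes and added 8: lost were CYP11A1, ANLN and SERPINF1 in BeWo, TJP1, MYOF and CDH5 in JEG3, and the differences of MX1 and TMEM183B. Without a filter 21 calls were lost, with pseudocounts 0.1 and 5 it was 8 each, and with the replicate block 12. The depth of the libraries is unknown, so it cannot be said which low values it limits.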

Other observations

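The scan of gene families, the test of coding-sequence sites and the restriction to splits balanced within the lines were chosen only after the result was seen, and the rank among all 7-mers was set as a test after the seed site shift was known. Among 206 families defined by a shared symbol prefix, several were called that the fixed lists do not hold, and none of these calls held with an estimated correlation. In JEG3, 16 of 29 MRPS genes, the small-subunit proteins of the mitochondrial ribosome, fell and 1 rose (camera adjusted p = 0.00402, and adjusted p = 0.936 with an estimated correlation). Of 14 NDUFA genes, nuclear subunits of respiratory complex I, 8 fell and 0 rose (adjusted p = 0.00934, and 0.936 with an estimated correlation). Of 26 SEC genes, many of them parts of secretory transport, 13 rose and 5 fell (adjusted p = 0.003, and 0.936 with an estimated correlation). TMED genes, cargo receptors of the early secretory pathway, rose in 5 of 10 cases in BeWo (adjusted p = 0.0158, and 0.976 with an estimated correlation) and in 6, with 1 fall, in JEG3 (adjusted p = 0.0382, and 0.936 with an estimated correlation). In BeWo the MRPS, NDUFA and SEC families did not pass by camera (adjusted p = 0.648, 0.213 and 0.345). Single genes there still moved mostly the same way as in JEG3. In BeWo 10 MRPS genes fell and 2 rose, 6 NDUFA genes fell and 0 rose, and 9 SEC genes rose and 5 fell. The 49 MRPL genes of the large mitochondrial ribosomal subunit passed in neither line (13 rose and 6 fell in BeWo, adjusted p = 0.124, and 3 rose and 13 fell in JEG3, adjusted p = 0.762).

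Among all 16356 7-mers scored over the 3' UTRs of 12569 genes, TGCACGA ranked 1 for the lowest score, the mean change of genes with the 7-mer minus that of the others over its standard error, on the change averaged over the lines, and also in each line, with GCACGAA at rank 2. This was the outcome that the hypothesis of seed-driven repression had named. On simulated data, made by shuffling the changes over genes and planting a shift of -0.3, the planted 7-mer ranked first in 10 of 10 runs. Shuffling removes any link between other 7-mers and the changes, so these runs did not test the rank against such links.

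A further hypothesis was that sites in coding sequences may also lower transcripts. Among the 11932 genes without a 3' UTR 6mer, 894 held a 7mer or 8mer in the coding sequence. Their median lay lower by -0.146 in BeWo and -0.081 in JEG3, and 0 of 299 control 7-mers counted in coding sequences gave a shift as low in either line. The lowest control values were -0.127 and -0.075. The pattern is consistent with weaker repression through such sites, as a hypothesis found and tested on the same data.

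The 5929 genes changed on average over both lines were set against other splits of the 8 libraries into 4 and 4. The comparable splits keep 2 libraries of each line on each side, as the real one does. There are 18 of them, too few for a share under 0.05, and 1, the real one, gave as many genes. The highest other count among them was 1217, from the split that crosses mimic and line and so measures the difference between the lines. A share over all 34 splits that could be fitted had been set as the bound before, but this was wrong by design, because 16 of them put 3 libraries of a line against 1. Splits that mix mimic and control libraries leave the mimic effect in the residual, which lowers their counts (median 0 over the other fitted splits).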
